A study of Mus musculus with 6 samples.

How the data were processed

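RNA of bladder epithelial cells from mice at postnatal day 7 was measured on 6 Affymetrix Mouse Genome arrays, 3 from DsRed-positive and 3 from DsRed-negative cells, after 2 rounds of amplification. Groups followed the sample titles and source descriptions, which also give the numbers 1, 2 and 5 in each group. According to the labels, the epithelium was loosened with trypsin, separated from the wall by dissection and digested to single cells. How DsRed-positive and DsRed-negative cells were parted is not stated. The values deposited by the authors were taken as linear probe set intensity, not on a log scale, because they were positive with 2 decimals and reached 500654 on 1 array. The submitters' processing notes name GCOS, whose version, algorithm settings and scaling target are not given in the sources used here. The mean of each array after trimming 2% at both ends was 1500.01 on all 6 arrays, so arrays had been scaled to a common level before deposition. Detection calls were not used here.

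An offset of 39.84, the 20th percentile of all values, was added before taking log2. The array medians then spanned 0.74 on the log2 scale (7.74 to 8.48), more than the limit of 0.2 set before the data were examined, so the log2 values were quantile normalized. The offset compresses ratios of dim probe sets, so folds are those of the offset and normalized values. Of 45101 probe sets, 64 controls were removed, and probe sets with a mean above the 33rd percentile (7.18) were tested, leaving 30175. Gene symbols came from the platform annotation, brought up to date through gene IDs: 34945 probe sets had 1 symbol (34741 of them matched through the gene ID and 204 kept as given), 932 had several and were used only as probe sets, and 9160 had none here. Each gene was represented by its single-gene probe set with the highest mean over all 6 arrays, giving 14222 genes. Of 6400 genes with more than 1 tested probe set, 11 had probe sets called in both directions. Genes without such a probe set here were not analysed. No coordinates are given, since the files name no genome build.

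Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided, both groups sharing 1 estimate of the spread), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Errors of log2 changes are standard errors of that fit, and errors of signals are SDs over 3 arrays. A floor for folds was set at the 95th percentile of 27 unspiked control probe sets of each array. Where all arrays of 1 group lay at or below it, the fold was computed against it and given as at least N-fold. This held for 174 of the higher and 317 of the lower genes. Single values per array were compared by an exact permutation test of the group means, for which the smallest p with 3 arrays against 3 is 0.1. Spike-in signal was the mean log2 of 9 hybridization control probe sets.

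Gene lists were fixed before the data were examined, 22 in all: uroplakins, superficial and differentiated urothelium, basal urothelium, general epithelium, tight junctions, apical vesicle traffic, fibroblast and matrix, smooth muscle and mural cells, endothelium, leukocytes, nerve and Schwann cells, erythroid cells, mitosis, DNA replication, immediate early and stress genes, cholesterol synthesis, lipid handling and fatty acid oxidation, retinoid signalling, hedgehog and BMP signalling, Notch signalling, xenobiotic metabolism and oxidative phosphorylation. A list of sex-linked genes was only described. Snx31 belonged to both the superficial and the vesicle traffic lists, and Shh to both the basal and the hedgehog lists. Lists were tested on 1 probe set per gene by camera with its preset correlation of 0.01, with adjustment over the 22 lists, and beside it by camera with an estimated correlation and by fry, which tests whether a list's genes move on balance in 1 direction without comparing them with other genes. Another 5 lists were written after the data had been seen: mast cells, cornified envelope and squamous keratins, mesenchymal transcription factors, Wnt and FGF signalling, and gap junctions.

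The genes named were chosen by a rule fixed before the data were examined: Upk1b, the 12 largest increases and the 12 largest decreases among called genes that moved the same way between all same-numbered arrays, all members of the uroplakin, superficial and basal lists, and the 4 members with the smallest p of every other list. Other members are named where they went against their list, did not pass or illustrate a gap, and these were chosen after their values were seen.

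The alternatives fixed beforehand were the values as deposited, centring each array on its median, the number as a replicate block, leaving out each array in turn, an offset of 1 or of the 50th percentile, no filter, a filter at the 50th percentile, eBayes with trend and robust estimation, array weights, the mean of all probe sets of a gene, probe sets without the suffixes _s_at and _x_at, an added log2 change of at least 1, adjusted p thresholds of 0.01 and 0.1, the other list tests, and the 3' minus middle signal of the control genes. Leaving out both arrays numbered 1 and taking the spike-in signal as a covariate were added after the data had been seen.

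The procedure was tested on simulated data with the means and spreads of the 30175 probe sets of this comparison, of which 200 were changed. It called 0 of 67 changed by 1 on the log2 scale, 10 of 67 (14.9%) changed by 2 and 63 of 66 (95.5%) changed by 4, and 6 of its 80 calls were false, the remaining call being 1 member of a list shifted in the simulation. With so few probe sets changed, the adjusted threshold was stricter than in the real comparison, where 5205 probe sets were called. The rates therefore do not give the sensitivity of that comparison, in which changes near 1 could pass, such as Cox4i1 (1.11). Changes of the smaller sizes could still be missed.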

Results

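Gene expression was measured in the bladder epithelium of mice at postnatal day 7. The labels name an allele of Upk1b, a uroplakin of the urothelial surface, as the reported gene, and divide the cells into DsRed-positive and DsRed-negative. Each group held 3 arrays, numbered 1, 2 and 5 in both, and each array measured RNA amplified in 2 rounds. The comparison asked which transcripts distinguished cells with the reporter from cells without it in bladder epithelium. The labels say that samples were not pooled but do not say that they came from separate animals, so p-values measure the spread between these samples. The number of arrays limits the precision.

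Upk1b itself separated the groups in every array. Its deposited signal was 48415, 98990.1 and 94871 in DsRed-positive arrays 1, 2 and 5, and 9626, 4515 and 2797 in the DsRed-negative arrays of the same numbers. On the normalized scale it was 16.62 ± 0.12 (SD, n = 3) against 12.35 ± 0.88, a log2 change of 4.27 ± 0.48 (SE), or 19.2-fold (adjusted p = 0.00105). All 4 of its probe sets rose. The DsRed-negative cells still gave Upk1b signal well above the control level, which was at most 8.03 on the log2 scale.

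**Figure D1:**
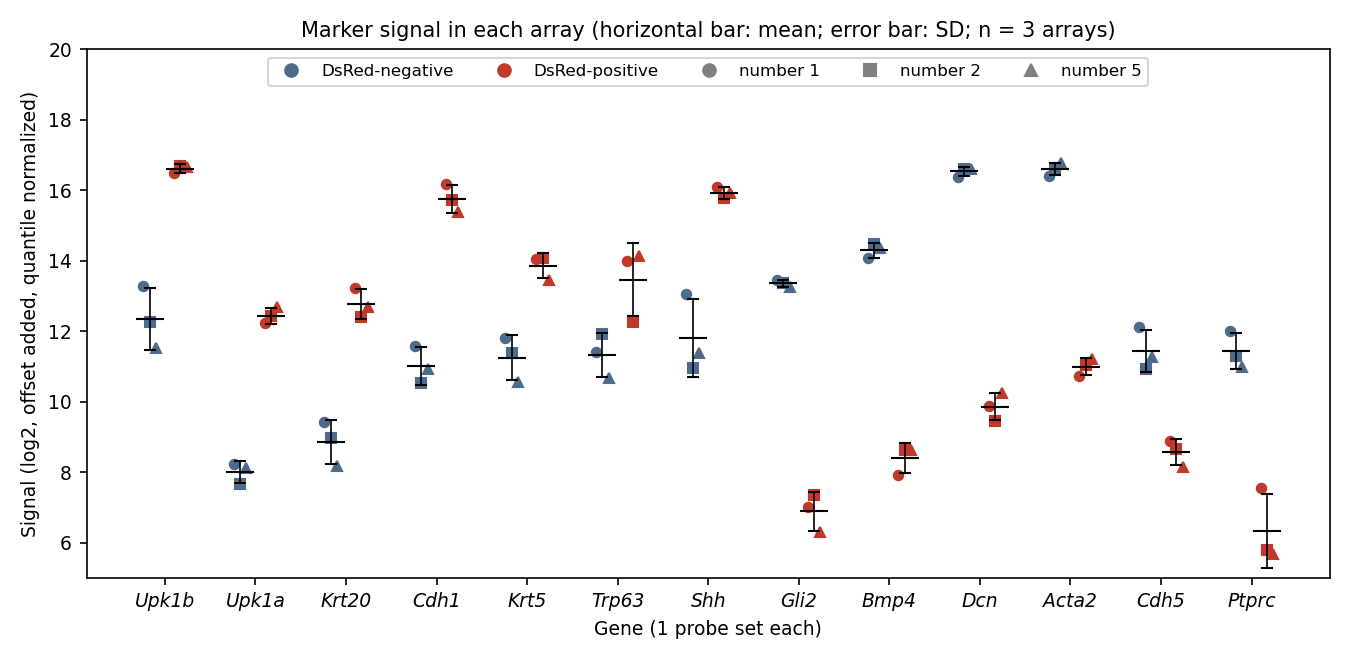
Normalized log2 signal of 13 genes in each of the 6 arrays, with the mean and SD of each group of 3; symbols give the array number. Uroplakins, Krt20, Cdh1, Krt5, Trp63 and Shh were higher in all DsRed-positive arrays than in the DsRed-negative ones, and Gli2, Bmp4, Dcn, Acta2, Cdh5 and Ptprc were lower.

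DsRed-positive cells carried an epithelial and urothelial profile, and DsRed-negative cells carried a profile rich in matrix, muscle, vessel and leukocyte transcripts. Of 14222 genes tested, 1310 were higher and 1603 lower in DsRed-positive cells. A change of at least 16-fold was found for 171 of the higher and 439 of the lower genes. All 2913 called genes moved the same way between arrays of the same number, which follows largely from the calling itself and is no separate evidence. By probe set, 2605 of 30175 were higher and 2600 lower, together 17.2% of those tested, by limma with Benjamini-Hochberg adjustment; 9536 had an unadjusted p under 0.05. Without DsRed-positive 1, 2 or 5 the higher genes numbered 623, 698 and 749, and without 1 of the DsRed-negative arrays 1121 to 1263. Without both arrays numbered 1, whose sex-linked signals stood apart, 485 genes were higher and 758 lower. The arrays of the other numbers were not left out together, so this drop cannot be credited to number 1 in particular. The scaling set the balance of directions: higher genes made up 45.0% of the called genes after quantile normalization, 37.6% with the values as deposited and 64.7% with each array centred on its median, since the median log2 signal was lower by -0.54 in the DsRed-positive arrays.

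**Figure D2:**
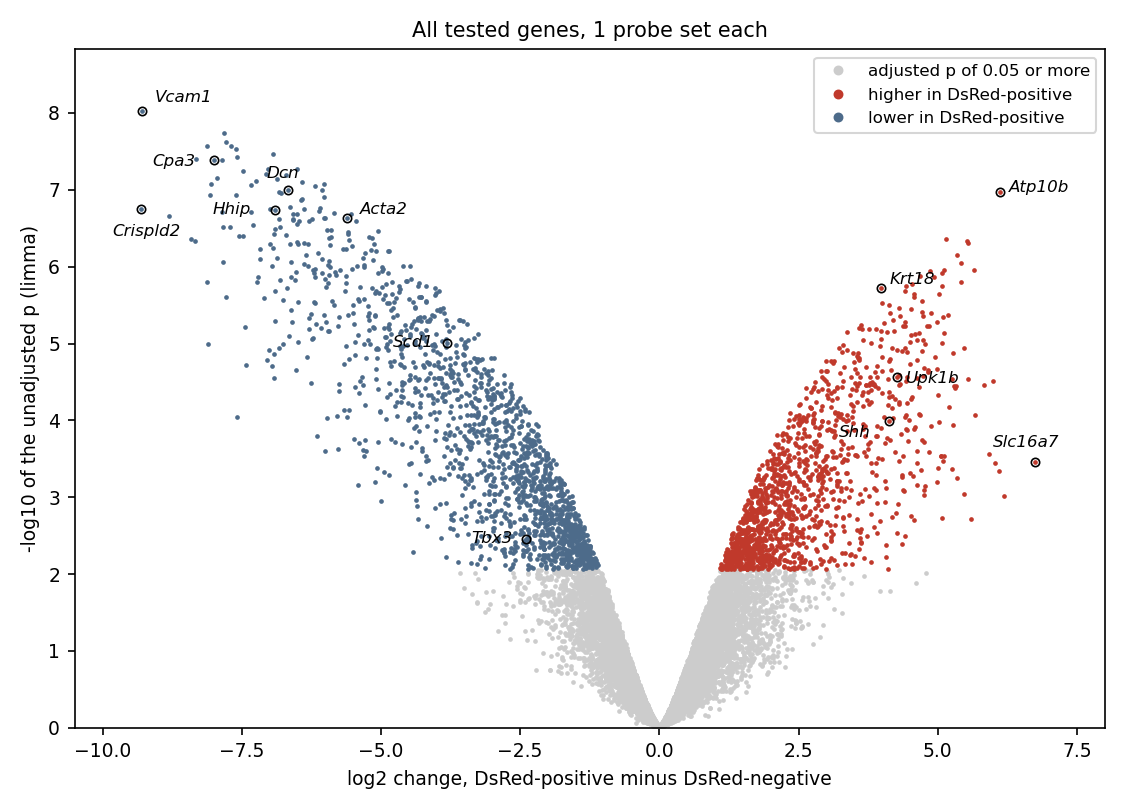
Log2 change (DsRed-positive minus DsRed-negative) of each tested gene against the -log10 of its unadjusted limma p, with called genes coloured by direction. The decreases reached -9.31 (Crispld2) and the increases 6.75 (Slc16a7).

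Among single genes, Slc16a7, a monocarboxylate transporter, had the largest fitted increase, a log2 change of 6.75 ± 1.10 (SE, adjusted p = 0.00549), and Sytl2, a Rab27 effector of vesicle docking, rose by 6.19 ± 1.19 (adjusted p = 0.0111). Atp10b, a lipid-flipping ATPase, rose by 6.12 ± 0.32, at least 28.7-fold over the control level because its DsRed-negative signal lay at or below that level. Cds1 (6.10), the sialyltransferase St8sia6 (6.03), Rab25 (5.98), Gsta2 (5.92), Cldn8 (5.83), Hsd17b2 (5.67), Jakmip1 (5.60), Dmgdh (at least 18.2-fold) and Slc16a12 (at least 13.1-fold) completed the 12 largest fitted increases. Jakmip1 (adjusted p = 0.0181) reached 0.0655 without DsRed-positive 1, and Sytl2 reached 0.0567 without the same array. Slc16a7 had a DsRed-negative signal of 10.175 in array 1. In arrays 2 and 5 it was 6.36 and 5.65, below their control levels of 7.69 and 8.03. The same pattern held for Gsta2 (9.465, 5.61 and 6.14), Jakmip1 (10.675, 6.08 and 5.71), Rab25 (8.62, 5.76 and 7.02) and Cldn8 (8.37, 5.71 and 6.16). Their sizes and ranks rest partly on signal below the control level, and their changes are smaller against DsRed-negative 1. Sytl2 and St8sia6 also lay below the control level in DsRed-negative 2 (6.32 and 6.08). Cds1 and Hsd17b2 did so in DsRed-negative 5 (6.01 and 5.97).

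The 12 largest fitted decreases included several secreted and matrix genes. Crispld2, a secreted protein, had a log2 change of -9.31 ± 0.52 (adjusted p = 9.28e-05). Vcam1, an adhesion molecule, changed by -9.29 ± 0.35 and was at least 229-fold lower against the control level. Cxcl14, a chemokine, and Cpa3, a protease of mast cells, were at least 171-fold and 98.9-fold lower. Collagen chain Col12a1 (-8.34), the Wnt antagonist Sfrp2 (-8.32), Lgals1 (-8.12), the collagen cross-linking enzyme Lox (-8.12) and the proteoglycan gene Vcan (-8.10) were also among the 12, with Bcat1, Klhl13 and Prss35 at least 128-fold, 122-fold and 120-fold lower. The Vcan probe sets did not all move alike: 4 fell and 1 had a value of 0.52. For Crispld2, DsRed-positive 1 and 2 (6.04 and 7.19) lay below their control levels (7.51 and 7.56). For Vcan, DsRed-positive 2 and 5 (5.71 and 6.06) lay below theirs (7.56 and 7.41). So did Col12a1 (6.69) and Lgals1 (7.43) in DsRed-positive 2, and Sfrp2 (7.16) and Lox (7.34) in DsRed-positive 5. The sizes of these changes rest partly on such signal.

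All 6 uroplakins, the plaque proteins of the urothelial surface, rose in DsRed-positive cells, with a mean log2 change of 3.90. The list shift had an adjusted p = 9.52e-06 by camera and an adjusted p = 0.0797 with an estimated correlation. Upk3b rose by 5.48 ± 0.54, Upk3a by 4.76 ± 0.51, Upk1a by 4.44 ± 0.34 and Upk2 by 3.20 ± 0.58. The smallest change was in Upk3bl, at 1.29 (adjusted p = 0.0367, and 0.125 without DsRed-positive 2). Adjusted over the list alone, all 6 were higher.

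Of 16 genes of superficial and differentiated urothelium, 15 rose and 1 fell, with a mean log2 change of 3.33. The camera test gave an adjusted p = 3.38e-10, and an adjusted p = 0.0797 with an estimated correlation. The keratins Krt7 (4.42 ± 0.39), Krt18 (3.98 ± 0.31) and Krt20 (3.91 ± 0.44) rose, as did Psca, at least 13.2-fold. Among transcription factors, Ehf (5.09), Grhl3 (4.57), Pparg (4.23), Ovol1 (3.79), Gata3 (3.45), Foxa1 (3.38), Klf5 (2.12) and Elf3 (1.83) rose. Krt19 (3.74) and the sorting nexin Snx31 (4.44) rose too. Krt8 rose by 2.05 (adjusted p = 0.0228) but lost its call with the values as deposited (0.0762) and in 5 of the 6 fits without 1 array, with adjusted p up to 0.0813 without DsRed-positive 1. With all 6 arrays, all 3 Krt8 probe sets were called higher. Tbx3, a T-box factor that is also found outside epithelium, was the member that fell, by a log2 change of -2.40 (adjusted p = 0.0276, and 0.0996 without DsRed-positive 1). The list alone gave the same counts, 15 and 1 when adjusted over the list alone.

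Of 11 basal urothelial genes, 7 rose, 1 fell and 3 did not pass, and the mean log2 change was 1.88. The list shift had an adjusted p = 0.00138 and an adjusted p = 0.238 with an estimated correlation. Shh, the signalling ligand made by urothelium, rose by 4.12 ± 0.56, the laminin chain Lamb3 by 3.67 ± 0.57 and the basal keratin Krt5 by 2.61 ± 0.43. Krt15 (2.60), Trp63 (2.13), Krt14 (2.03) and Itga6 (1.88) rose as well, but each lost its call without DsRed-positive 1, with adjusted p from 0.0570 to 0.160. Cd44, a hyaluronan receptor that leukocytes and stroma also express, fell by a log2 change of -2.56 ± 0.50 (adjusted p = 0.0118). Col17a1 (2.17) and Itgb4 (2.20, with DsRed-negative signal at the control level) did not pass. Dst had a value of -0.18 on the probe set used, while 3 of its 4 probe sets were higher. Adjusted over the list alone, 9 were higher and 1 lower.

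Genes of epithelial identity rose almost throughout. Of 19 general epithelial genes, 18 rose and 1 did not pass (Pkp3, 3.23, adjusted p = 0.0513). E-cadherin (Cdh1) rose by 4.73 ± 0.41, the microvillus protein Prom2 by 4.53 ± 0.34, and the protease Prss8 and the plakophilin Pkp1 at least 16.1-fold and 15.1-fold. All 19 were higher when adjusted over the list alone. The mean log2 change was 3.80, with an adjusted p = 6.41e-14 by camera and 0.0371 with an estimated correlation.

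Of 13 tight junction genes, 9 rose, none fell and 4 did not pass. The mean log2 change was 2.79, with an adjusted p = 3.45e-06, and an adjusted p = 0.0797 with an estimated correlation. Claudins Cldn8 (5.83 ± 0.67), Cldn7 (4.54 ± 0.55) and Cldn4 (3.51 ± 0.40) and the polarity gene Pard6b (4.57 ± 0.64) rose, while Cldn12 had a value of -0.16. Adjusted over the list alone, 11 were higher. Among 16 genes of apical vesicle traffic, 7 rose and 9 did not pass, with the same 7 as a count adjusted over the list alone. Rab27b, which acts in uroplakin vesicle delivery, rose by 4.52 ± 0.42, the motor Myo5b by 3.89 ± 0.35 and Sytl1 by 3.72 ± 0.43, whereas Rab27a (0.36), Vamp7 (0.35) and Snap23 (-0.17) did not pass. This list had a mean of 2.11 but a median of 1.06, and its adjusted p was 3.68e-05, or 0.0371 with an estimated correlation.

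**Figure D3:**
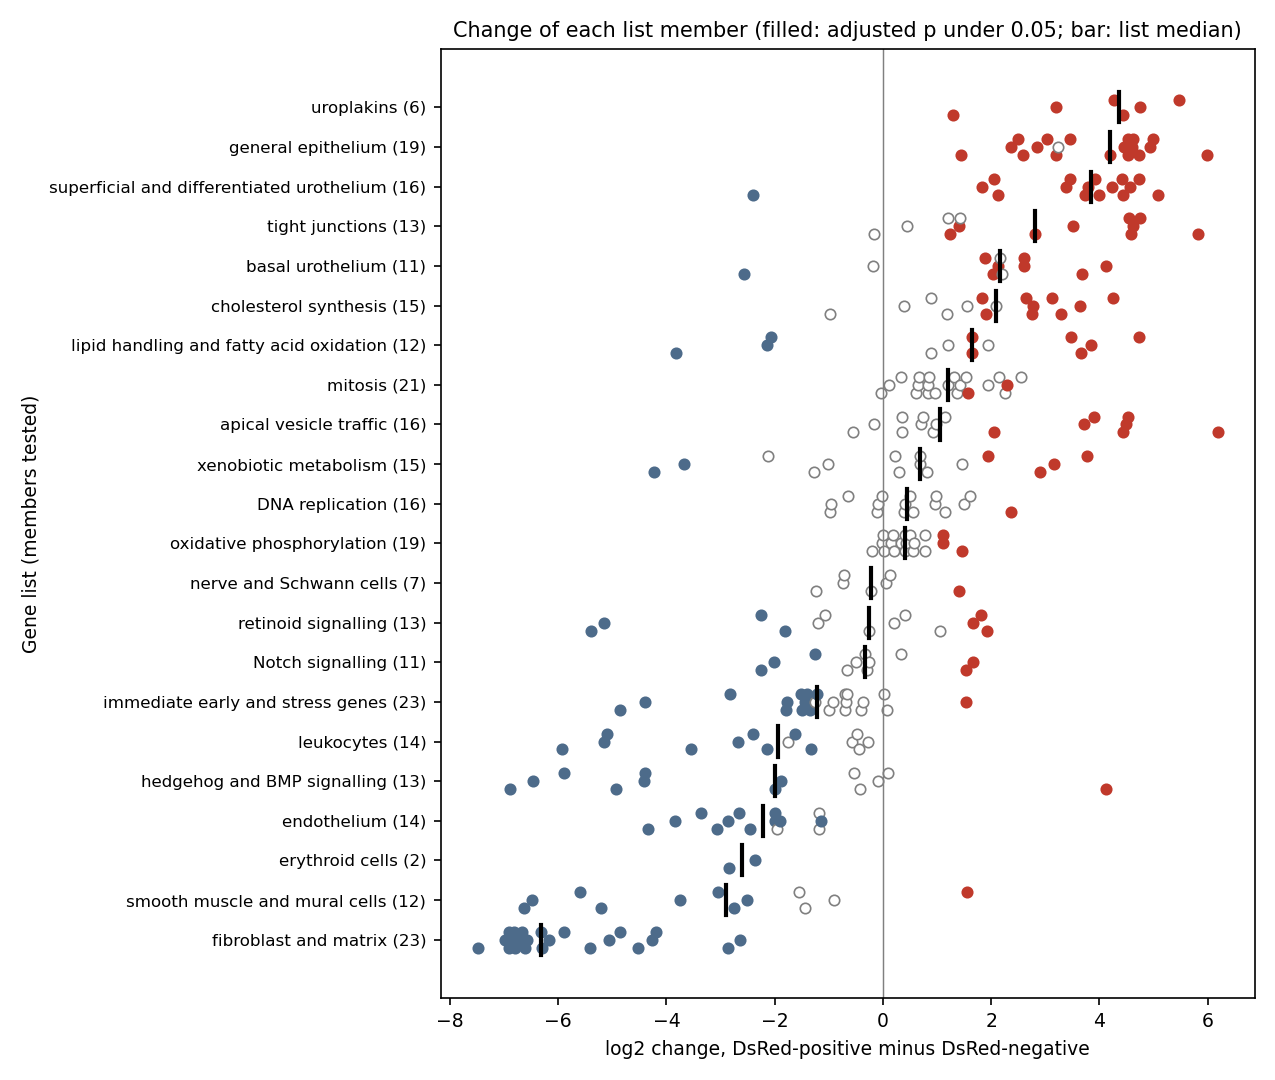
Log2 change (DsRed-positive minus DsRed-negative) of every measured member of the 22 lists, filled where the adjusted p was under 0.05, with a bar at each list's median. Medians ran from -6.31 for fibroblast and matrix genes to 4.35 for uroplakins.

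Markers of other cells of the bladder wall were high in the DsRed-negative arrays. All 23 fibroblast and matrix genes fell in DsRed-positive cells, with a mean log2 change of -5.82 and all 23 lower when adjusted over the list alone (adjusted p = 5.72e-22, and 0.0371 with an estimated correlation). The collagen chain Col5a2 changed by -6.84 ± 0.40, Sparc by -6.79 ± 0.35, decorin (Dcn) by -6.67 ± 0.34 and periostin (Postn) by -6.57 ± 0.38. In the DsRed-negative arrays, Col5a2 had a log2 signal of 16.69 ± 0.04 (SD) against 9.85 ± 0.62 in the DsRed-positive ones, and Dcn 16.53 ± 0.13 against 9.86 ± 0.39.

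Among 12 genes of smooth muscle and mural cells, 8 fell, 1 rose and 3 did not pass, with a mean of -3.19 and 9 lower and 1 higher when adjusted over the list alone. The pericyte receptor Pdgfrb (-6.63 ± 0.43) and the contractile genes Actg2 (-6.49 ± 0.62), Acta2 (-5.61 ± 0.32) and Tagln (-5.21 ± 0.46) fell. Rgs5, a pericyte marker and regulator of G-protein signalling named after its value was seen, went against the list at 1.56 (adjusted p = 0.0439, and 0.0625 with the values as deposited and 0.157 without DsRed-positive 1). All 4 Rgs5 probe sets were higher, from 0.75 to 2.93, and 3 of them were called. The list's adjusted p was 2.92e-06, or 0.0371 with an estimated correlation. Endothelial genes fell in 11 of 14 cases, in 6 without DsRed-positive 1 and in 14 when adjusted over the list alone, with a mean of -2.42. Tek, the angiopoietin receptor, changed by -3.85 ± 0.55, the endothelial claudin Cldn5 by -3.06 ± 0.35, VE-cadherin (Cdh5) by -2.87 ± 0.42 and the phosphatase Ptprb by -2.65 ± 0.38 (list adjusted p = 4.39e-07, and 0.0371 with an estimated correlation).

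Leukocyte genes fell in 9 of 14 cases, 10 when adjusted over the list alone, with a mean of -2.39 (adjusted p = 4.55e-06, and 0.0371 with an estimated correlation). The common leukocyte antigen Ptprc changed by -5.09 ± 0.57, the class II gene H2-Aa by -5.15 ± 0.47 and Cd52 by -3.55 ± 0.41. Laptm5 changed by -5.94 ± 0.41 on its brightest probe set; 3 of its 5 probe sets fell and another gave 0.069. Both measured erythroid genes, Hbb-b2 (-2.84 ± 0.53) and Alas2 (at least 1.87-fold lower, adjusted p = 0.0496, and 0.151 without DsRed-positive 5), fell, and both were lower when adjusted over the list alone, but the list did not pass (mean -2.60, or -1.87 with Alas2 at its bound, adjusted p = 0.0563, and 0.0117 by fry). Of 7 nerve and Schwann cell genes none fell and 1 rose, Mbp at 1.40 (adjusted p = 0.0473, and 0.149 without DsRed-positive 1), and 0 passed when adjusted over the list alone. Of the 6 Mbp probe sets, 5 were higher, 4 of them called, with values from -0.75 to 3.56. Mbp encodes myelin basic protein, and its locus also makes transcripts outside myelinating cells. Prph (-1.23), S100b (-0.74) and Elavl4 (-0.73) did not pass. The nerve list had a mean of -0.19 and an adjusted p = 0.807.

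Hedgehog signalling was split between the groups by role. The ligand Shh was higher in DsRed-positive cells (4.12 ± 0.56), while the target and inhibitor Hhip and the transcription factor Gli2 were at least 58.3-fold and 58.1-fold lower. The receptor Ptch1 (-4.93 ± 0.39), Gli1 (at least 10.6-fold) and the growth factor Bmp4 (-5.90 ± 0.36) also fell. Of 13 hedgehog and BMP genes, 8 fell, 1 rose and 4 did not pass, counts that were the same when adjusted over the list alone. The mean was -2.59, with an adjusted p = 4.26e-05 and 0.0371 with an estimated correlation. The matrix genes above were lower in the same arrays.

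Retinoid genes moved in both directions and the list as a whole did not pass (mean -0.78, median -0.26, adjusted p = 0.317, and 9.13e-04 by fry). Aldh1a2, which makes retinoic acid, changed by -5.39 ± 0.64, the carrier Rbp4 by -5.16 ± 0.32 and Aldh1a1 by -2.25 ± 0.34. Stra6, the receptor for the carrier, was at least 1.57-fold lower. Dhrs3 (1.66), the retinoid receptor Rxra (1.81) and the binding protein Crabp2 (at least 2.12-fold) rose, each with a call that was lost without at least 1 array (adjusted p up to 0.0578 and 0.0674 without DsRed-positive 1 for the first and second, and 0.138 without DsRed-positive 2 for Crabp2). In all, 3 of 13 rose and 4 fell, or 4 and 6 when adjusted over the list alone.

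Notch genes were also divided, with 2 of 11 higher and 3 lower, the same counts when adjusted over the list alone, but only 1 of the 5 calls was kept in every fit without 1 array. The ligand Dll1 fell by a log2 change of -2.25 ± 0.40 (adjusted p = 0.00849), and Notch4, a receptor of endothelium, was at least 1.76-fold lower. Notch1 (1.66) and Jag1 (1.53) rose, with adjusted p of 0.0251 and 0.0271, which became 0.0927 without DsRed-positive 5 and 0.110 without DsRed-positive 1. The list mean was -0.37 (adjusted p = 0.343, and 0.0302 by fry), and 0.03 with each array centred on its median.

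Immediate early and stress genes were lower in DsRed-positive cells, where 11 of 23 fell, 1 rose and 11 did not pass. Socs3, a feedback inhibitor of cytokine signalling, changed by -4.87 ± 0.32, Klf2 by -4.39 ± 0.52, Egr2 by -2.83 ± 0.44 and the phosphatase Dusp1 by -1.77 ± 0.32. Fos (-0.70) and Jun (-0.38), among the genes most used as signs of acute stimulation, did not pass, and neither did Egr1 (-0.99). Egr1 was called lower with the values as deposited (-1.82, adjusted p = 0.0141) and with each array centred on its median (-1.28, 0.0379). Fos and Jun did not pass with either scaling. Klf6, named after its value was seen, rose (1.53, adjusted p = 0.0169, and 0.0762 without DsRed-positive 1). All 5 Klf6 probe sets were higher, and 3 of them were called. Of the 12 calls of the list, 5 were kept in every fit without 1 array. Klf4 was lost in all 6 of these fits (adjusted p up to 0.136), Egr3 and Jund in 5 (0.117 and 0.152), Ier2 in 4 (0.0989), and Btg2 and Junb in 3 (0.0789 and 0.0807). With each array centred on its median 7 fell, and with trend and robust estimation 17. Adjusted over the list alone, 14 were lower and 1 higher. The mean was -1.27, with an adjusted p = 1.21e-05 and 0.0456 with an estimated correlation. The matrix, endothelial and leukocyte genes above were lower in the same arrays.

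Of 15 cholesterol synthesis genes, 9 rose, none fell and 6 did not pass, or 12 rose when adjusted over the list alone. The list mean was 2.09, with an adjusted p = 1.23e-05, and an adjusted p = 0.220 with an estimated correlation. The sterol enzymes Msmo1 (4.25 ± 0.89), Sc5d (3.65 ± 0.44), Fdft1 (3.12 ± 0.50) and Fdps (2.76 ± 0.37) rose, and Srebf2, the regulator of the pathway, rose by 1.83. Insig1, which restrains that regulator, had a value of -0.98 and Hmgcs1 of 0.38, and neither passed. Only Sc5d, Fdft1 and Fdps, 3 of the 9, kept their calls in every fit without 1 array. Without DsRed-positive 1 the calls of Msmo1 (adjusted p = 0.0732), Idi1 (0.0757), Cyp51 (0.0757), Srebf2 (0.0837) and Sqle (0.0920) were lost, and Dhcr7 lost its call in 5 of the 6 fits (up to 0.118, without DsRed-positive 2).

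Fatty acid genes went both ways, with 6 of 12 higher and 3 lower, or 9 and 3 when adjusted over the list alone. The peroxisomal enzyme Ehhadh (4.72 ± 0.40), the mitochondrial dehydrogenase Acadl (3.47 ± 0.44) and the fatty acid carrier Fabp4 (3.65 ± 0.46) rose. Scd1, which desaturates fatty acids, changed by -3.82 ± 0.37, and Angptl4 (-2.07) and the fatty acid transporter Cd36 (-2.15) fell, these 2 losing their calls without DsRed-positive 2 (0.0759) and DsRed-positive 1 (0.104). The mean was 1.25 (adjusted p = 0.0162, adjusted p = 0.160 with an estimated correlation, and 0.0551 with each array centred on its median).

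Detoxifying enzymes did not shift together (mean 0.24, adjusted p = 0.343). Of 15, 4 rose and 2 fell, or 4 and 4 when adjusted over the list alone. The glutathione transferases Gstm1 (3.77 ± 0.34) and Gsta4 (3.15 ± 0.45) rose, whereas Gstt1 (-4.23 ± 0.37) and the cytochrome Cyp1b1 (-3.67 ± 0.55) fell. Of 19 oxidative phosphorylation genes, 3 rose and 16 did not pass, among them Cox5a (0.79) and Ndufb8 (-0.21), and 0 passed when adjusted over the list alone. The 3 were Uqcrfs1 (1.47), Atp5b (1.12) and Cox4i1 (1.11), of which Atp5b (0.0882) and Cox4i1 (0.146) lost their calls with the values as deposited. The mean of the 19, 0.46, had an adjusted p = 0.0307 and an adjusted p = 0.336 with an estimated correlation. The list call was lost without DsRed-negative 1 (0.109), DsRed-positive 2 (0.0526) or DsRed-positive 5 (0.0638), and the 3 genes reached 0.118, 0.153 and 0.161 with 1 array left out.

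Cell cycle genes were uneven among the DsRed-positive arrays. Of 21 mitosis genes, 2 rose and 19 did not pass, and 1 was higher when adjusted over the list alone. The ubiquitin-conjugating enzyme Ube2c rose by 2.28 ± 0.41 (adjusted p = 0.00852) and the kinesin Kif20a by 1.57 (adjusted p = 0.0497, and 0.139 without DsRed-positive 5), while Cdk1 (1.42) and Ccnb2 (1.37) did not pass. The proliferation marker Mki67 was 14.61 in DsRed-positive 5 against 12.68 and 11.72 in DsRed-positive 1 and 2, and 12.16 ± 0.17 (SD) in the DsRed-negative arrays. The mean of 1.21 had an adjusted p = 0.00255, an adjusted p = 0.464 with an estimated correlation, 0.146 by fry, and 0.0668 (mean 0.66) without DsRed-positive 5. Among 16 DNA replication genes only the thymidylate synthase Tyms rose, at least 1.74-fold (adjusted p = 0.0266, and 0.0951 without DsRed-positive 5), while Gins2 (1.49), Mcm3 (1.15) and Rrm1 (0.98) did not pass. None passed when adjusted over the list alone. That list had a mean of 0.47 and an adjusted p = 0.259 by camera. Its result depended on the array left out: the mean was 0.98 with an adjusted p of 0.00857 without DsRed-positive 1, but the adjusted p was 0.948 without DsRed-positive 5.

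In all, 16 of 22 lists passed by camera, 10 higher and 6 lower, and 8 of these held with an estimated correlation: general epithelium, apical vesicle traffic, fibroblast and matrix, smooth muscle and mural cells, endothelium, leukocytes, hedgehog and BMP, and immediate early and stress genes. By fry, 18 passed. With members at the control level set at their bounds, the median of the general epithelium list was 3.92 in place of 4.19 and the mean of the hedgehog and BMP list -2.39 in place of -2.59, and, apart from the erythroid genes, the means of the other lists moved by at most 0.11. Of the 180 list members called, 126 were called in all 6 fits that left out 1 array. Every member with an adjusted p below 0.0111 was among them, and none with an adjusted p above 0.0118 was.

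The arrays differed by group in measures other than single genes. The mean log2 signal of the spike-in controls, which rises as the amount of sample RNA in the hybridization falls, was 13.73 ± 0.81 (SD, n = 3) in DsRed-positive and 15.37 ± 1.02 in DsRed-negative arrays (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows; 0.15 after Benjamini-Hochberg over 6 measures). The 3' minus 5' log2 signal of Actb was 2.25 ± 0.20 against 2.96 ± 0.25 (exact permutation p = 0.1) and that of Gapdh 3.85 ± 0.24 against 3.52 ± 0.16 (exact permutation p = 0.2). The 3' minus middle signal went the other way for Gapdh, at 1.66 ± 0.10 against 1.91 ± 0.09 (exact permutation p = 0.1), and differed less for Actb, at 0.87 ± 0.18 against 1.07 ± 0.29 (exact permutation p = 0.4). Across probe sets, which are not independent replicates, the correlation between arrays was 0.921 to 0.940 within DsRed-positive, 0.845 to 0.892 within DsRed-negative and 0.674 to 0.766 between groups. The first principal component held 62.3% of the variance and separated the groups, and the second, with 15.6%, spread the DsRed-negative arrays.

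Signals of Xist and Eif2s3y divided the arrays by number and not by group. Xist, which is transcribed from the inactive X chromosome, had deposited signals of 45699 and 28183 in DsRed-negative 1 and DsRed-positive 1, and of 203 to 546 in the other 4 arrays. Eif2s3y, on the Y chromosome, had signals of 3.83 and 31.2 in the arrays numbered 1 and of 3309 to 8043 in the others. The 2 other Y-linked genes measured were dim and did not follow this division throughout. Kdm5d had a signal of 22.7 in DsRed-positive 1, but one of 28.4 in DsRed-negative 5, which was lower than in DsRed-negative 1, and of 240.2 to 881 in the 3 other arrays not numbered 1. Uty had 7.79 and 27.9 in the arrays numbered 1, 33.2 in DsRed-negative 2 and 168 to 574 in the rest. All 6 samples were labelled male. In the fit without the numbers none of these 4 genes passed between the groups, with log2 changes of -0.41 (Xist), 0.87 (Eif2s3y), 1.49 (Kdm5d) and 0.80 (Uty) and adjusted p of 0.341 or more. The SE there, 2.37 for Xist and 2.22 for Eif2s3y, holds the difference between the numbers. Between arrays of the same number, Xist was lower and Eif2s3y higher in DsRed-positive cells in 3 of 3 cases.

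**Figure D4:**
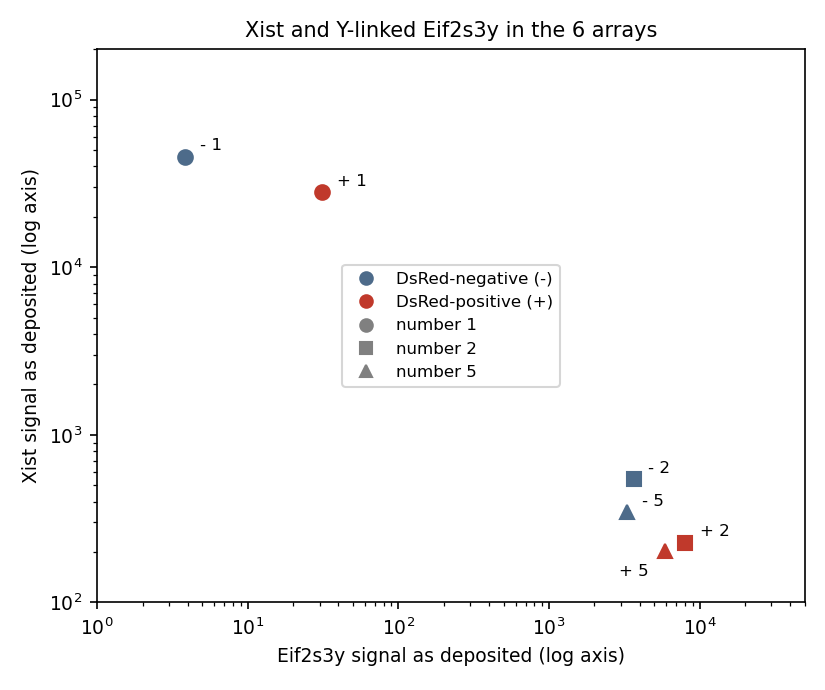
Deposited Xist signal against deposited Eif2s3y signal in the 6 arrays, both on log axes. Both arrays numbered 1 had Xist at or above 28183 and Eif2s3y at or below 31.2, and the other 4 had the reverse.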

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

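The tests that left out both arrays numbered 1 or took the spike-in signal as a covariate were chosen only after the data had been seen. Of the list results over all alternatives, 433 kept their direction and side of the threshold, 15 lost the call and 14 gained one; of the named gene results, 2291 kept both, 198 lost the call, 23 gained one and 1 reversed. Every called list kept its direction, and Upk1b and the fibroblast and matrix list kept their calls, under each alternative run. Centring on the median called 4873 probe sets and 2569 genes higher. Without both arrays numbered 1, 922 probe sets and 485 genes were higher and 1213 and 758 lower, with fewer arrays in the fit. With the spike-in covariate, which itself differed between the groups, these counts were 468, 267, 1062 and 698. An adjusted p threshold of 0.01 gave 988 probe sets and 558 genes higher and 1492 and 957 lower, and a threshold of 0.1 gave 4011 probe sets higher. Leaving out 1 array gave 1145 (without DsRed-positive 1) to 2582 (without DsRed-negative 1) higher and 1713 (without DsRed-positive 1) to 2405 (without DsRed-negative 2) lower probe sets, and 623 to 1263 higher genes, for the same arrays as the higher probe sets. Camera with an estimated correlation left 8 lists and ended the calls of the uroplakins (mean 3.90, adjusted p = 0.0797), superficial urothelium (3.33, 0.0797) and basal urothelium (1.88, 0.238). The p of this test also rose in lists whose estimated correlation lay below the preset 0.01. For apical vesicle traffic (-0.008) the unadjusted camera p went from 1.84e-05 to 0.0101, and for smooth muscle and mural cells (-0.072) from 6.63e-07 to 0.00634. The lost calls therefore cannot be put down to correlated members alone. Laptm5 reversed to 0.069 (adjusted p = 0.917) without probe sets ending in _s_at and _x_at, because another of its probe sets was then used. The cause of the other changes was not tested. The replicate block, in which arrays of the same number are paired, called 2473 genes, of which 2349 were shared (80.6% of the genes called without it). Beside 122 named gene results that kept their direction and side of the threshold, the block ended the call of 11. It is given only here because the correlations of the deviations from the group means were 0.145, 0.037 and 0.053 for the numbers 1, 2 and 5. These were below the 0.1 set for pairing in 2 of 3. All 6 arrays still correlated best with their own number, and both arrays numbered 1 shared the unusual Xist and Eif2s3y signals. Pairing by number therefore stays possible, and the fit without the block leaves any difference between numbers in its spread. Xist and Eif2s3y did not pass with the block either (adjusted p = 0.450 and 0.147). Of the genes called, 93.1% kept the call with the values as deposited and 32.1% with the covariate. Without DsRed-positive 1, 2 or 5 the shares were 57.6%, 63.8% and 63.6%. For the control genes, the group difference in 3' minus middle signal was -0.25 for Gapdh, against 0.34 for 3' minus 5', and -0.21 for Actb, against -0.72. Signals near the control level limit folds, which are lower bounds only where all arrays of 1 group lay at or below it. Where only some arrays did, the change is given without a bound and rests partly on such signal. Examples are Wnt2 (5.74 and 6.07 in DsRed-positive 1 and 5) and Actg2 (6.92 and 5.53 in DsRed-positive 1 and 2).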

Other observations

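The 5 lists and all tests here were chosen only after the data had been seen, except the splits of the arrays and the test of dim probe sets. Some squamous genes were higher in DsRed-positive cells. Of 12 genes of the cornified envelope and squamous keratins, 7 rose and 5 did not pass, and 7 were higher when adjusted over the list alone. Involucrin (Ivl) rose by a log2 change of 5.29 ± 0.61 (SE), envoplakin (Evpl) by 4.31 ± 0.70, periplakin (Ppl) by 3.24 ± 0.51 and Sprr1a by 3.20 ± 0.39, while Lor (-0.47) and Krt10 (0.21), which mark keratinized skin, did not pass. The list mean was 1.86, with an adjusted p = 0.00461 over the 5 lists and an adjusted p = 0.0573 with an estimated correlation. Gap junction genes exchanged members: Gjb6 (5.36 ± 0.36) and Gjb2 (4.66 ± 0.54) rose, while Gja1 (-2.97 ± 0.40) and Gjc1 (-5.40 ± 0.81) fell, and the other 2 of 6 did not pass; adjusted over the list alone, 2 were higher and 3 lower. That list did not pass (median -1.29, mean -0.16, adjusted p = 0.672), and fry placed its balance in the opposite direction (adjusted p = 0.244).

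Some transcription factors and signals of mesenchyme were higher in the DsRed-negative arrays. Of 14 mesenchymal transcription factors, 7 fell in DsRed-positive cells and 7 did not pass, including Zeb1 (at least 87.5-fold lower), Foxf1 (-6.12 ± 0.34) and Tcf21 (-5.31 ± 0.51), while Snai2 had a value of -0.15; adjusted over the list alone, 9 were lower and 1 higher (mean -2.51, or -2.28 with members at the control level set at their bounds, adjusted p = 1.08e-04, and 0.0390 with an estimated correlation). Meox2 went the other way at 1.96 but did not pass (adjusted p = 0.0651). Nr2f1 (-2.27) lost its call in 2 of the 6 fits without 1 array (adjusted p up to 0.0722, without DsRed-positive 1). Of 16 Wnt and FGF genes, 10 fell and 1 rose, or 11 and 3 when adjusted over the list alone (mean -2.47, or -2.33 with such bounds, adjusted p = 4.15e-04, and 0.0390 with an estimated correlation). The antagonist Dkk2 was at least 56.1-fold lower, Wnt2 changed by -7.00 ± 0.70 and the growth factor Fgf7 was at least 9.64-fold lower, whereas Wnt5a rose by 3.66 ± 0.50. Of 7 mast cell genes, Cpa3 (at least 98.9-fold), Hdc (at least 17.6-fold) and Cma1 (-5.23 ± 0.45) were lower and 4 did not pass, among them Kit (-0.75) and Gata2 (1.03), with 3 lower when adjusted over the list alone (median -0.98, mean -2.79, or -2.35 with such bounds, adjusted p = 0.00738, and adjusted p = 0.0589 with an estimated correlation).

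Of the 10 splits of the 6 arrays into 3 and 3, 1, the split by DsRed, gave as many called probe sets as were reported. It gave 5205 by limma and the highest of the others gave 0, with 405 to 924 probe sets at an unadjusted p under 0.05. The other splits mix the groups, so the DsRed difference enters their spread and makes calls unlikely from the start. So few splits also cannot give a share under 0.05, and no conclusion is drawn from them.

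The DsRed-negative samples were labelled as bladder epithelial cells, yet matrix genes were far higher in them than in the DsRed-positive samples. The differences remained with the spike-in signal of all 6 arrays as a covariate. The list median was then -6.03 for fibroblast and matrix genes (median SE of a member 0.615, and 21 of 23 still lower). For general epithelium it was 3.51 (median SE 0.584, and 14 of 19 still higher). The spike-in signal itself differed between the groups, so this fit cannot fully part the amount of RNA on the arrays from the group. A candidate explanation is RNA of other cells of the bladder wall in the DsRed-negative material: the lists for mural cells, endothelium and leukocytes were lower in DsRed-positive cells too, with medians of -1.95 or further from 0 and adjusted p of at most 0.0371 with an estimated correlation, although the nerve list did not pass. The dissection named in the labels would remove such cells at least in part, and no gate is described. The share of such cells was not estimated, and whether some of these transcripts came from DsRed-negative urothelial cells was not tested.

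Both arrays numbered 1 carried a sex-linked signal at odds with the label male. Xist was higher there by at least 6.19 on the log2 scale than in any of the other 4 arrays, and Eif2s3y was lower by at least 5.46, values that female tissue would give, so a wrong label for number 1 is a candidate source. A mixture of male and female cells is unlikely, since Eif2s3y in these arrays lay below the control level (highest difference -1.19 on the log2 scale) and reached at most 0.598% of the mean of the others. Sex did not separate the groups, as each held 1 such array. Differences due to sex itself were not tested, since they coincide with number 1.

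Basal urothelial genes had smaller log2 changes than uroplakin and superficial genes. The median log2 change of the 11 basal genes was 2.17 against 3.95 for the 22 others, a difference of -1.78 (permutation test over genes, which are not independent replicates, two-sided p = 0.0182). As a set the basal genes were not dim: their median log2 signal was 13.46 in DsRed-positive and 11.33 in DsRed-negative arrays. The superficial list had 13.85 and 10.86, and the uroplakins 14.03 and 9.28. These medians argue against dim signal as the cause for the list as a whole. It could not be ruled out for single members such as Col17a1 and Itgb4, with 9.36 and 9.37 in DsRed-positive arrays. A line of log2 change on DsRed-positive signal was fitted to 54 other epithelial genes. The basal genes lay at a median of -0.98 from it, with 9 of 11 below the line. This was just over 2 of its errors of 0.465, the SD over the square root of the number of basal genes. That error treats genes as independent and is likely too small for a median of correlated genes (estimated correlation 0.32). Leaving out Cd44, Dst and Itga6, which other wall cells may express, kept a difference of -1.55 (permutation test, two-sided p = 0.0415). A relative excess of basal cells among DsRed-negative urothelium stays open as a hypothesis that was not tested apart from the other cells present.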
